A study of Oryza sativa with 12 samples.

How the data were processed

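Gene expression was measured in spikelets of the rice cultivar Hayayuki at the booting stage on 12 two-colour Agilent arrays. Per the labels, low-Tw plants had stood for 2 weeks in irrigation water of 18 °C, ahead of panicle initiation, and chilled plants were kept in air at 12 °C for 5 days at booting. Aliquots of 450 ng of RNA were labelled. Each of 3 comparisons had 4 arrays, with the same dye orientation throughout, so a dye effect specific to a gene is part of every direct ratio. Chilled normal-Tw RNA in Cy3 was set against chilled low-Tw RNA in Cy5, non-chilled normal-Tw RNA in Cy3 against non-chilled low-Tw RNA in Cy5, and non-chilled normal-Tw RNA in Cy3 against chilled normal-Tw RNA in Cy5.

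Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1, and the deposited intensity values are the mean brightness of each spot and the median of its local background, on a linear scale and without correction. The scanner's own ratio is a log10 value of Cy5 over Cy3 after detrending, background subtraction and dye normalization, per the file headers. The deposited values of the series hold that log10 ratio unchanged on every array, so its scale and direction are known, and its array medians lie between -0.00472 and 0. The processed signal columns, which the authors deposited as intensity after the same steps, were used only to average brightness where the deposited ratio was the source.

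Spot brightness was corrected with normexp (offset 50) and normalized within each array by loess, with control spots and spots carrying a scanner outlier mark at weight 0, in limma 3.58.1 under R 4.3.3 with statmod 1.5.0 and data.table version 1.17.8. Control spots (2007 of 45151) and marked spots were left out, and spots of a probe were averaged, which gave 42418 probes. A probe was tested when it lay well above background on all 4 arrays in at least 1 channel of 1 kind of array and had a usable spot on every array (101 probes had none on some array). This left 36091 probes of 24804 loci. Genes carry the locus and description of the array files, which can be old. The gene reference at hand pairs none of these loci with a symbol. A locus is represented by its brightest probe. Among loci with at least 2 called probes, 6.81% to 11.1% had calls in opposite directions, depending on the comparison.

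The main test, set before the data were examined, was a limma fit of the log2 ratio on all 12 arrays with 1 coefficient per comparison, a two-sided moderated test and Benjamini-Hochberg adjustment over the 36091 probes, with calls at an adjusted p of 0.05. The difference between the low-Tw effects of chilled and non-chilled spikelets is a contrast of 2 coefficients, in which a dye effect equal on all arrays cancels. Chilling in low-Tw plants was never hybridised directly and was summed over all 3 comparisons, which keeps 1 dye effect. p-values measure only the spread between these samples. Each comparison lay on its own slide, and the chilling arrays were scanned on another day than the others, so slide and comparison cannot be told apart.

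After the data were examined, a second test was added, because the channels of each condition fell into 2 RNA profiles rather than the 4 biological replicates of the labels. It takes the 2 profiles of each condition as the replicates, pools the spread over the 4 conditions and moderates it across probes. Profiles were recognised from the values and served only as units of replication and for leaving arrays out. Named genes are said to have risen or fallen only where both tests called them. Counts of list members are from the main test, with those from RNA profiles as replicates given in the same order as profile counts.

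Both tests were run on simulated data with the observed spread between and within RNA profiles and 200 changed probes among the 36091. Of the unchanged probes, the main test called 7.69% (low Tw, chilled), 7.51% (low Tw, non-chilled), 7.90% (chilling), 7.13% (difference of low-Tw effects) and 0.181% (chilling in low-Tw plants). The false share of the calls depends on the number of changed probes set here. In the direct comparisons, 93.4% (low Tw, chilled), 93.2% (low Tw, non-chilled) and 93.4% (chilling) of the probes called by the main test were false, as were 93.4% for the difference of low-Tw effects and 27.4% for chilling in low-Tw plants. With RNA profiles as replicates the false shares were 7.74%, 4.46%, 5.56%, 8.11% and 4.64%. That test recovered 86.6%, 86.6%, 91.0%, 52.2% and 89.6% of the 2-fold changes in the same order, and 49.3%, 40.3%, 38.8%, 7.46% and 31.3% of the 1.5-fold changes. The simulation drew its spread from the profile model itself and gave all conditions the same spread, which favours the second test, above all for non-chilled low-Tw RNA.

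A total of 29 gene lists was fixed beforehand from loci and from words in the descriptions: small heat shock proteins, HSP70, HSP90 and HSP100 chaperones, DnaJ co-chaperones and chaperonins, prolyl isomerases, heat stress factors, DREB1/CBF and other cold regulators, LEA and dehydrin proteins, abscisic acid, gibberellin, jasmonate, cytokinin, reactive oxygen scavenging, glutathione S-transferases, sugar and starch, aquaporins, tapetum and pollen wall, mature pollen, meiosis, floral MADS-box and pistil genes, photosynthesis, histones and DNA replication, cytosolic ribosomal proteins, circadian clock, lipid transfer proteins, phenylpropanoids, WRKY factors, pathogenesis-related proteins, proteasome and ubiquitin, and fatty acid desaturases. The heat shock, chaperone, prolyl isomerase and heat stress factor lists draw on what is remembered of the published study and are not independent evidence. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists within a comparison. Fry does not set a list against the other genes. With low Tw in chilled spikelets it passed small heat shock proteins (fry adjusted p = 4.03e-12), the larger chaperones (2.62e-10) and also DnaJ genes (1.63e-05), which camera did not pass (0.316). Other fry values are left out. Descriptions that named a different gene led to 3 loci and 3 word patterns being removed after medians had been seen, which took pathogenesis-related proteins from 136 to 68 members, photosynthesis from 77 to 53, jasmonate from 21 to 18, meiosis from 16 to 15 and abscisic acid from 17 to 16.

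Genes named were, per comparison, the 8 with the largest rise and the 8 with the largest fall among called probes with an informative description, the same direction on all 4 arrays (for the difference, all 4 arrays of 1 comparison beyond all 4 of the other) and signal above background, up to 4 members with the smallest p in each list described, and the FK506-binding immunophilin Os04g0352400 and HSP101 in every comparison. A bound is given where a channel was not well above background on any of its 4 arrays, from channel means after loess and Aquantile against the lowest signal well above background, and is open to dye bias.

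Alternatives fixed beforehand were no background correction, an offset of 16, the deposited log10 ratio from either source, median centring, Aquantile and scale between arrays, no dim-probe filter, a strict one, fits on the arrays of a comparison only, array weights, an intensity trend, the replicate number as a block, a separate-channel fit with a dye term (intraspot correlation 0.177 from 3000 probes, for some of which the estimate did not converge), each array left out, and a 2-fold threshold. Alternatives chosen after the data were seen were the RNA profiles as replicates, leaving out the arrays of a profile, lists without the removals, and chilling in normal-Tw set against chilling in low-Tw plants.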

Results

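Rice is sensitive to cool weather at the booting stage, when pollen forms inside the spikelet. The experiment asked whether cool irrigation water early in plant life changes how spikelets respond to later chilling. Plants grew in water of low or normal temperature (Tw) and were then chilled at booting or left unchilled, which gives 4 conditions. RNA from pairs of conditions was compared on 12 arrays, 4 per comparison. Between 79.9% and 84.7% of probes were well above background in Cy3, and between 82.8% and 85.6% in Cy5. No spot was saturated, and the number of arrays, and of different RNA samples on them, limits the precision.

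Log2 ratios of the 4 arrays correlated across probes with r of 0.912 to 0.957 for low Tw in chilled spikelets and 0.869 to 0.942 for chilling in normal-Tw plants. For low Tw in non-chilled spikelets r ran from 0.362 to 0.899. Probes are not independent replicates. In each condition the 4 arrays of a comparison divided into 2 pairs with nearly equal profiles. The Cy5 channel of non-chilled low-Tw spikelets differed between arrays 1 and 3 and arrays 2 and 4 with an SD of 0.47 over probes, against 0.06 and 0.05 for the other pairings of the same arrays. This was the largest division. In the other channels the SD was 0.20 to 0.22, against 0.05 to 0.09 for the other pairings. The matching divisions of normal-Tw chilled RNA on separate slides correlated at r = 0.828, and those of normal-Tw non-chilled RNA at r = 0.765. Between conditions r lay from -0.22 to 0.26. The series description gives 4 biological replicates per treatment, so results of probes and genes are given with arrays and with these 2 RNA profiles per condition as replicates. List tests were run only with arrays as replicates, so their p-values treat arrays that share RNA as independent. For lists, only the counts of called members are also given with profiles.

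**Figure D1:**
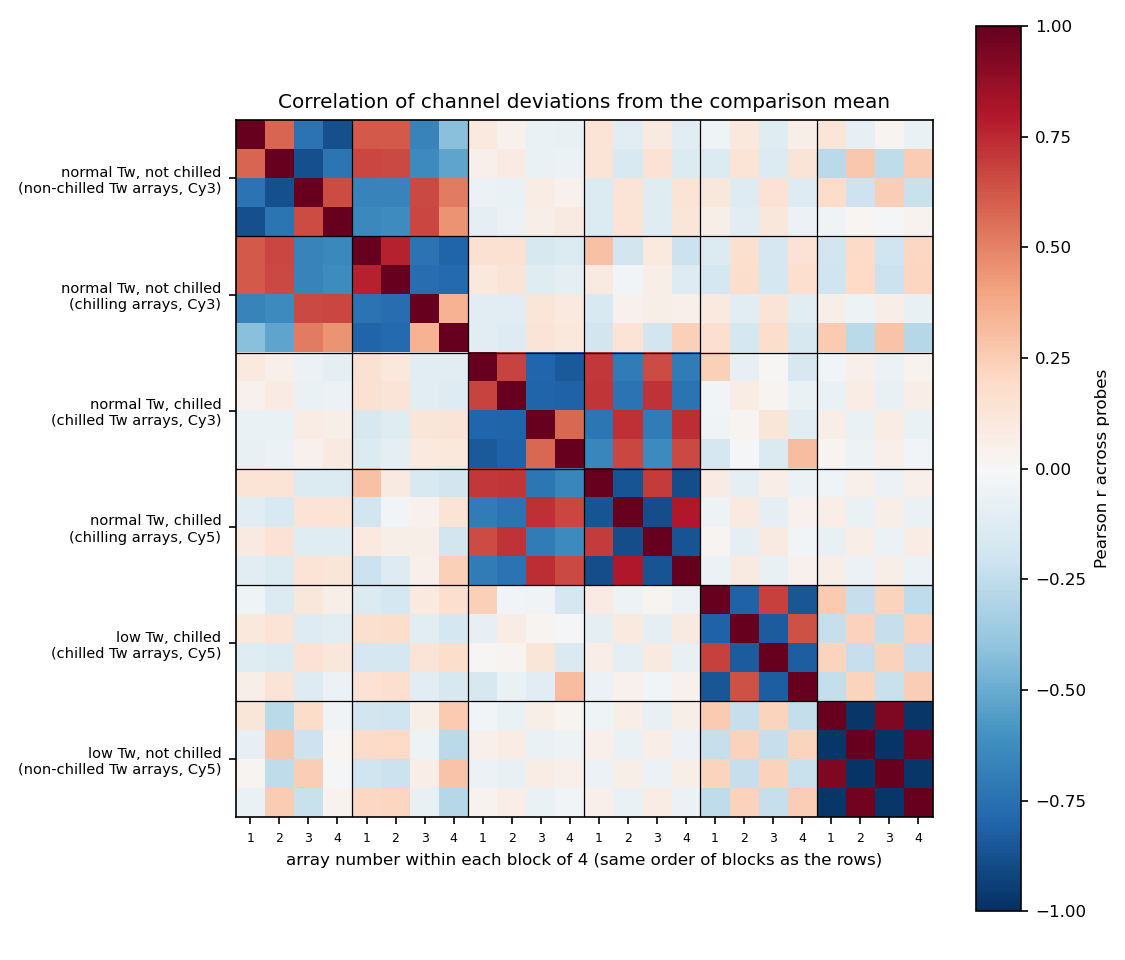
Pearson correlation across probes (colour, from -1 to 1) between channel deviations from the mean of their comparison; each block of 4 holds the arrays of 1 channel. Red and blue squares recur between the blocks of the same condition on different slides, where the matched divisions correlate at 0.765 and 0.828.

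The first comparison set chilled spikelets of low-Tw plants against chilled spikelets of normal-Tw plants. It asks what the earlier cool water left behind once the spikelets were cold. Heat shock proteins are chaperones that keep other proteins folded under stress, and most genes of the largest falls named here encode them. Small heat shock and photosynthesis genes had lower medians and clock genes a higher one, but no list kept its call with an estimated correlation (adjusted p = 0.771, 0.771 and 0.783). The main test called 13871 probes higher and 13580 lower, and with RNA profiles as replicates 10392 were higher and 10051 lower. At least 2-fold changes with profiles as replicates numbered 1465 higher and 2222 lower.

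The FK506-binding immunophilin gene Os04g0352400 had the largest fall among the named genes, with a log2 ratio of -7.10 ± 0.09 (SE, n = 4 arrays, or 0.11 with profiles as replicates). Its adjusted p was 8.05e-14 in the main test, and 1.56e-06 with profiles as replicates. HSP81-1 (Os04g0107900) had a log2 ratio of -6.11 and HSP101 (Os05g0519700) one of -3.88, each lower on 4 of 4 arrays. The small heat shock protein genes Os01g0136000 (-6.13), Os03g0266900 (-5.91), Os01g0136200 (-5.25) and Os02g0758000 (-5.08) fell on every array as well. The LEA3 family gene Os01g0314800 had a log2 ratio of -6.23 (adjusted p = 0.0153 with profiles as replicates), and the Bowman-Birk inhibitor gene Os01g0123900 one of -5.21 (0.0284). Both p-values use the spread pooled over all conditions, also that of low-Tw non-chilled RNA, which these arrays do not hold. Genes that rose included a GroES-like gene (Os04g0372700, 3.80), heat shock factor gene Os01g0733200 (3.69), a DnaJ gene (Os04g0675400, 3.61), the Myb genes Os04g0583900 (3.55) and Os01g0971800 (3.15), and a response regulator gene (Os09g0532400, 3.47). The thiazole synthesis gene Os07g0529600 rose by 3.04 and the lysine decarboxylase-like gene Os04g0518800 by 2.96.

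Of 27 small heat shock protein genes, 20 were called lower and 4 higher (profile counts 19 and 4), with a median log2 ratio of -2.16 (camera adjusted p = 2.28e-05). This list, like that of the HSP70, HSP90 and HSP100 chaperones (median -0.33, 19 lower and 7 higher of 30, profile counts 14 and 5, adjusted p = 0.00971), is not independent evidence. Here and for the lists of the other comparisons, counts adjusted over the list alone were the same as the counts given, except where they are stated. Photosynthesis genes had a median of -0.79 (38 lower and 5 higher of 53, profile counts 35 and 4, adjusted p = 1.14e-06). Among them the chlorophyll-binding genes Os11g0242800, Os09g0346500 and Os02g0197600 had log2 ratios of -2.01, -2.10 and -2.08. LEA and dehydrin genes had a median of -0.59 (adjusted p = 0.00465), with dehydrin gene Os02g0669100 at -2.35 and dehydrin gene Os01g0702500 at -2.64. Clock genes had a median of 1.09, 9 higher and 2 lower of 11, profile counts 7 and 1 (adjusted p = 0.0212), with the FKF1 gene Os11g0547000 up by 1.75. Floral MADS-box and pistil genes had a median of 0.35, 15 of 18 called higher, profile count 11 (adjusted p = 0.00465), including the PISTILLATA-like gene Os01g0883100 at 0.88. Mature pollen (-0.28) and phenylpropanoid genes (-0.34) passed with lower medians. So did jasmonate genes (-0.62), but not with the removed members put back (-0.50, adjusted p = 0.0582). With a dye term the calls of the MADS-box and pistil list (adjusted p = 0.0626), phenylpropanoids (0.0626), reactive oxygen (0.0806), jasmonate (0.113) and proteasome genes (0.544) were lost. The proteasome call was also lost with the deposited ratio (0.0815). Without profile 1 of normal-Tw chilled RNA the calls of reactive oxygen (0.057) and phenylpropanoid genes (0.0639) were lost, and without profile 2 of low-Tw chilled RNA that of reactive oxygen genes (0.0728). Reactive oxygen (-0.15), cytosolic ribosomal (-0.20) and proteasome genes (-0.13) also passed, but under median centring their medians became 0.12, 0.20 and 0.23. With an estimated correlation no list kept its call, the adjusted p-values of these 12 lying between 0.771 and 0.878.

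The next comparison set chilled against non-chilled spikelets of normal-Tw plants. It gives the response to cold without earlier cool water. Lists of heat shock, late embryogenesis and ribosomal protein genes had higher medians and those of histone and clock genes lower ones, but with an estimated correlation none passed (adjusted p between 0.607 and 0.754). The main test called 12656 probes higher and 11664 lower, against 7912 and 7179 with profiles as replicates.

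HSP81-1 rose most among the named genes, by 6.09 ± 0.07 (SE, n = 4 arrays, or 0.08 with profiles as replicates). Its adjusted p was 5.26e-14 in the main test, and 1.05e-06 with profiles as replicates. The small heat shock genes Os01g0184100, Os03g0266900 and Os01g0136000 rose by 5.39, 5.07 and 4.69, HSP26 (Os03g0245800) by 4.37 and HSP101 by 3.66. The immunophilin gene Os04g0352400 rose by 3.51. The raffinose synthase gene Os01g0170000 rose by 5.30, the ERF gene Os01g0868000 by 4.63 and the LEA3 gene Os01g0314800 by 5.63 (adjusted p = 0.0305 with profiles as replicates). That p-value uses the spread pooled over all conditions, while on the chilling arrays the LEA3 gene ranged from 5.40 to 5.88. The largest falls were in the DnaJ gene Os01g0606900 (-4.15), the RCc2 gene Os10g0551800 (-4.08), the thiazole synthesis gene Os07g0529600 (-3.74), the exonuclease gene Os04g0225100 (-3.58), the RING finger gene Os10g0445400 (-3.38), the GroES-like gene Os04g0372700 (-3.34), the BTB/POZ gene Os01g0908200 (-3.28) and the response regulator gene Os09g0532400 (-3.25). On 4 of 4 arrays each of these moved the same way.

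Cytosolic ribosomal protein genes had a median of 0.40, with 139 of 158 called higher and 4 lower, and 140 and 4 adjusted over the list alone, profile counts 112 and 2 (camera adjusted p = 2.31e-16). Small heat shock genes had a median of 1.11 (17 higher, 7 lower, profile counts 16 and 7, adjusted p = 0.001), the larger chaperones 0.41 (19 higher, 4 lower, profile counts 17 and 1), and DnaJ and chaperonin genes 0.18 (59 higher, 23 lower of 102, 60 higher adjusted over the list alone, profile counts 44 and 10). LEA and dehydrin genes had a median of 0.60, with dehydrin genes Os11g0454300 and Os01g0702500 up by 2.55 and 2.43, but with the strict filter on dim probes the list did not pass (adjusted p = 0.0638). Histone and replication genes had a median of -0.47 (46 lower and 8 higher of 64, with 10 higher adjusted over the list alone, profile counts 39 and 6, camera adjusted p = 1.55e-05), among them histone H4 gene Os05g0466600 at -0.94. Under median centring the histone median was -0.09 and no longer passed (adjusted p = 0.067). Clock genes had a median of -0.85 (9 lower, 1 higher, profile counts 7 and 1), with FKF1 at -2.65 and the gigantea homologue Os01g0182600 at -1.31. None of these 7 lists passed with an estimated correlation (adjusted p between 0.607 and 0.754).

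**Figure D2:**
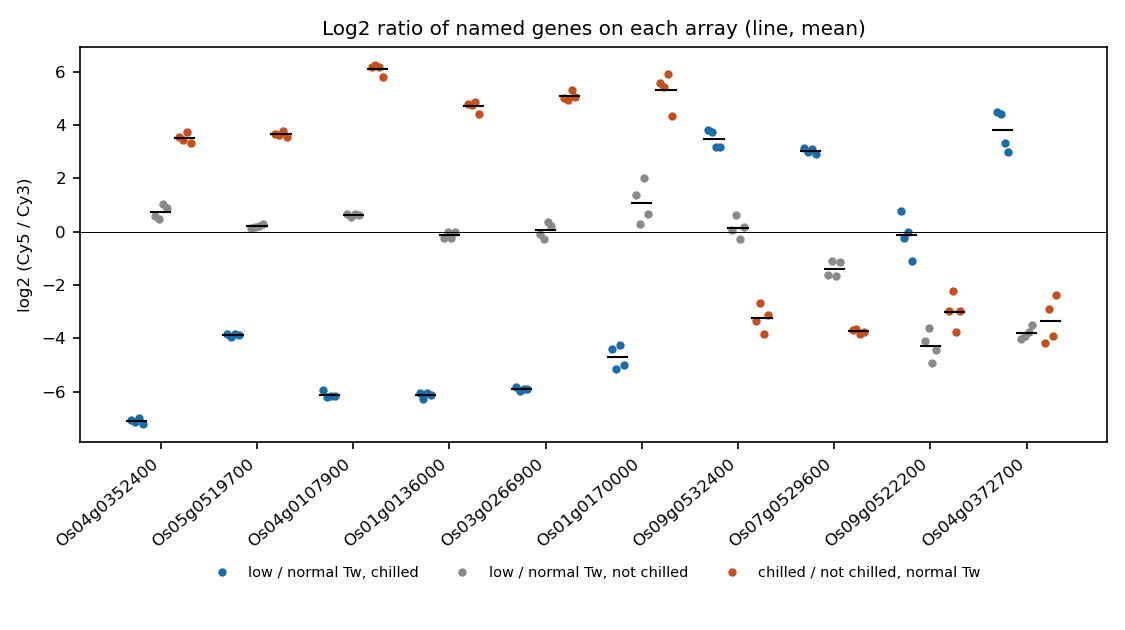
Log2 ratio (Cy5 over Cy3) of named genes on each array, 4 arrays per comparison; points are arrays and lines are means. HSP81-1 (Os04g0107900) lies near -6.11 for low Tw in chilled spikelets, near 6.09 for chilling in normal-Tw plants and near 0.62 for low Tw in non-chilled spikelets.

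Low against normal Tw in non-chilled spikelets asks what cool water left behind without later chilling. DREB1/CBF proteins regulate the response to cold, and early light-inducible proteins protect the photosynthetic apparatus. Single genes of both kinds were among the largest changes, but the list of cold regulators did not pass (median -0.26, camera adjusted p = 0.179, and 0.919 with an estimated correlation). Among the 22 heat shock genes that chilling raised at least 2-fold in normal-Tw plants, the median log2 ratio was 0.16. The main test called 9842 probes higher and 8809 lower, and only 2218 and 2033 remained as counts with profiles as replicates. The 2 profiles of low-Tw non-chilled RNA differed over 2-fold for 946 probes, against 112 to 160 in the other conditions. The second test pools the spread over conditions, so its p-values can be too small here and its counts too high. The same holds for the difference of low-Tw effects and for chilling in low-Tw plants, which use this RNA too.

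DRE-binding protein 1A (Os09g0522200) had a log2 ratio of -4.28 ± 0.29 (SE, n = 4 arrays, or 0.45 with profiles as replicates). Its adjusted p was 1.04e-06 in the main test, and 0.00732 with profiles as replicates. Others that fell on 4 of 4 arrays were the GroES-like gene Os04g0372700 (-3.80), the CBF-like gene Os09g0522000 (-3.78), the RING finger gene Os02g0681200 (-3.01), the ERF gene Os04g0610400 (-2.96), the CRT/DRE factor gene Os04g0572400 (-2.90), the patatin gene Os03g0640000 (-2.90) and the CAF1 ribonuclease gene Os04g0684900 (-2.81). The early light-inducible genes Os01g0246400 and Os07g0178800 rose by 3.78 and 2.85. Another 6 genes had large mean ratios that did not pass with profiles as replicates. The NAM-domain gene Os11g0126900 (3.24, adjusted p = 0.21) ranged from 0.44 to 6.01 over the 4 arrays, the PBZ1 gene Os12g0555500 (3.02, 0.178) from 0.57 to 5.53 and the glucanase gene Os05g0375400 (2.86, 0.0832) from 0.92 to 4.77. The O-methyltransferase gene Os10g0118200 (2.64, 0.154) ranged from 0.64 to 4.56, GRAB2 (Os07g0684800, 2.55, 0.213) from 0.30 to 5.04 and the Bowman-Birk gene Os01g0123900 (3.15, 0.22) from 0.15 to 5.97. In Cy3 the Bowman-Birk gene was not well above background on any array, which gives a mean at least 8.5-fold higher in low-Tw RNA. That mean rests on arrays 1 and 3, which carry the same RNA profile. Without both arrays the log2 ratio was 0.37 for the Bowman-Birk gene (adjusted p = 0.516), 0.32 for GRAB2 (0.361), 0.46 for the NAM-domain gene (0.301) and 0.74 for the O-methyltransferase gene (0.0784). Without array 1 or array 3 alone the Bowman-Birk gene's log2 ratio was 2.24 or 2.21 (adjusted p = 0.0587 and 0.06), and that of GRAB2 1.89 or 1.73 (0.0509 and 0.0505). The immunophilin gene Os04g0352400 rose by 0.74 (adjusted p = 0.016 with profiles as replicates), and HSP101 had 0.20 (0.113).

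Lists with lower medians were histones and replication (-0.12, 27 lower and 5 higher of 64, profile counts 3 and 1) and proteasome genes (-0.08, 23 lower and 7 higher of 55, profile counts 2 and 1). Under median centring both medians lay above 0 (0.09 and 0.16), and the proteasome list passed there as higher (camera adjusted p = 0.041), the histone list not (0.696). Glutathione S-transferases (0.19, 26 higher and 7 lower of 50, profile counts 9 and 3, but -0.0018 with a dye term and 0.04 under median centring, adjusted p = 0.513) and ribosomal genes (0.08, 53 higher and 13 lower, 49 and 12 adjusted over the list alone, profile counts 5 and 2) were higher. Each had a camera adjusted p of 0.047, and 0.919 with an estimated correlation. Single arrays decided these calls. Without array 1 of this comparison the adjusted p was 0.0807 for glutathione S-transferases, 0.164 for histones and 0.22 for proteasome genes. Without array 3 it was 0.0553 for glutathione S-transferases, and without array 2 or array 4 it was 0.0741 or 0.313 for ribosomal genes. Leaving out array 1 or array 4 of low Tw in chilled spikelets, which takes part in the same fit, gave 0.0522 or 0.0541 for glutathione S-transferases. The strict filter on dim probes also ended each of these calls (adjusted p between 0.0504 and 0.0562), and so did leaving out the arrays of single RNA profiles (0.0566 to 0.993). Those of glutathione S-transferases and ribosomal genes were lost without background correction (0.0554 and 0.06) and with scaling between arrays (0.0556 and 0.0583). Without the filter on dim probes those of glutathione S-transferases (0.137) and proteasome genes (0.0558) were lost. With a dye term those of histones (0.0653) and proteasome genes (0.961) were lost, and the latter also with the deposited ratio (0.146).

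The difference between both low-Tw effects asks whether earlier cool water acts otherwise in chilled than in non-chilled spikelets. Negative values mean that low Tw lowered a gene more, or raised it less, in chilled spikelets. Lists of heat shock, LEA and photosynthesis genes had negative medians and that of clock genes a positive one, but each lost its call with an estimated correlation (adjusted p = 0.687). The main test called 11854 probes positive and 12368 negative, against 7333 and 7539 with profiles as replicates.

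The immunophilin gene Os04g0352400 had a difference of -7.84 ± 0.12 (SE, n = 4 arrays of each kind, or 0.16 with profiles as replicates). Its adjusted p was 1.53e-12 in the main test, and 7.77e-06 with profiles as replicates. HSP81-1 had a difference of -6.73 and HSP101 one of -4.07. On the positive side were the GroES-like gene Os04g0372700 (7.59), the CBF-like gene Os09g0522000 (6.24), the DnaJ gene Os01g0606900 (5.00), the RING finger gene Os02g0681200 (4.85), the heat shock factor gene Os01g0733200 (4.67), the FMO gene Os04g0223500 (4.67) and the ERF gene Os04g0610400 (4.65). Small heat shock genes had a median of -2.32 (17 negative, 6 positive, profile counts 17 and 4, camera adjusted p = 2.1e-05), larger chaperones -0.46, LEA genes -0.59, photosynthesis genes -0.80 (38 negative, 7 positive, profile counts 33 and 5, adjusted p = 2.49e-06), jasmonate genes -0.61, mature pollen genes -0.27, ribosomal genes -0.27, phenylpropanoid genes -0.48 (36 negative and 8 positive, with 7 positive adjusted over the list alone, profile counts 23 and 3), MADS-box and pistil genes 0.26 and clock genes 1.497. None of these 10 lists passed with an estimated correlation (adjusted p between 0.687 and 0.722). The MADS-box and pistil call (adjusted p = 0.0486) was lost without array 2, 3 or 4 of low Tw in chilled spikelets (0.0523, 0.0593, 0.0712), array 1 or 3 of low Tw in non-chilled spikelets (0.0636, 0.0646) and array 2 or 3 of chilling (0.0515, 0.0525). It was also lost with scaling between arrays, where the median was 0.15 (adjusted p = 0.285), under median centring (0.0864), with the deposited ratio (0.0638), with the strict filter on dim probes (0.0602), with the replicate number as a block (0.0514) and with a dye term (0.276). Leaving out the arrays of 1 RNA profile ended it for 4 of the 8 profiles (0.0519 to 0.115). The jasmonate call was lost with a dye term (0.0789). With the removed members put back, the median was -0.40 for jasmonate and -0.71 for photosynthesis genes. The mature pollen call was lost without the filter on dim probes (median -0.05, adjusted p = 0.0991) and without profile 1 of normal-Tw (0.0519) or low-Tw non-chilled RNA (0.0668).

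**Figure D3:**
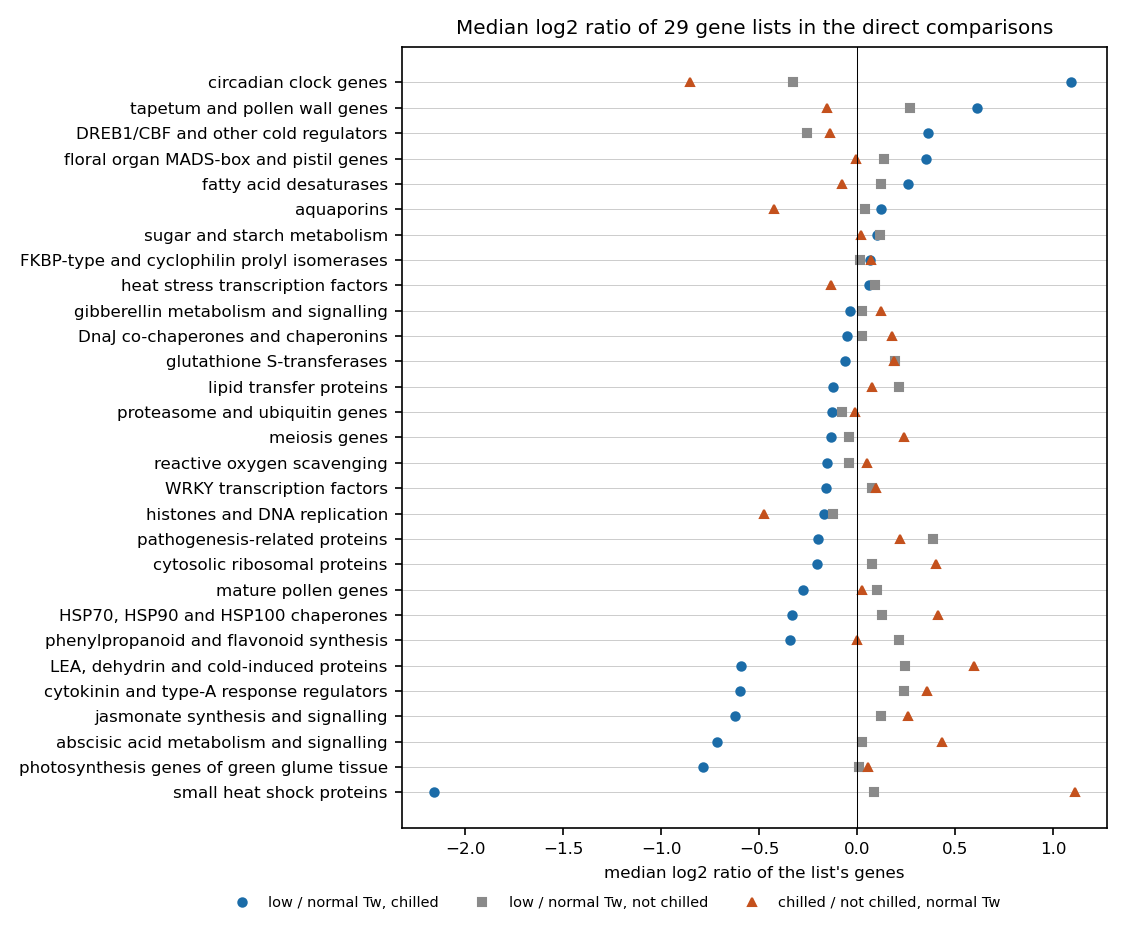
Median log2 ratio of the genes of each of 29 gene lists in the direct comparisons, 1 point per list and comparison. Small heat shock proteins lie at -2.16, 1.11 and 0.08 for low Tw in chilled spikelets, chilling, and low Tw in non-chilled spikelets.

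The lists that passed in no comparison had these medians for the same difference: abscisic acid -0.59, cytokinin -0.45, pathogenesis-related -0.37, lipid transfer -0.26, WRKY -0.09, tapetum and pollen wall 0.32, and cold regulators 0.89. Heat stress factors had a median of -0.10 and sugar and starch genes one of -0.08. Median, mean and test direction differed in sign for the prolyl isomerases (0.01, -0.19, up), gibberellin (0.09, -0.07, down), aquaporins (0.19, -0.0027, up), meiosis (0.06, -0.02, up), desaturases (0.04, -0.16, down) and heat stress factors (mean -0.02, up). The histone list (-0.07, -0.0019, up) did so too. With the removed members put back, the median was -0.10 for pathogenesis-related, -0.55 for abscisic acid and 0.14 for meiosis genes.

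Chilling in low-Tw plants was estimated indirectly. The main test called 9838 probes higher and 9619 lower, against 9344 and 9150 with profiles as replicates. Photosynthesis genes had a median of -0.71 (39 lower and 7 higher, with 40 lower adjusted over the list alone, profile counts 39 and 7, camera adjusted p = 2.75e-08). Phenylpropanoid genes had -0.36 and mature pollen genes -0.30, which was -0.07 without the filter on dim probes (adjusted p = 0.0501). Histones had -0.44, but 0.0012 under median centring. Small heat shock genes had -0.39, but 0.04 under median centring and 0.09 with scaling between arrays, and with a dye term their call was lost (-0.31, adjusted p = 0.0826). None passed with an estimated correlation (adjusted p = 0.798). The immunophilin gene Os04g0352400 fell by 4.34. HSP101 had a log2 ratio of -0.42, but 0.13 under median centring, 0.79 with scaling between arrays and 0.27 with a dye term.

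Probes that rose with chilling in normal-Tw plants were often negative in the difference of low-Tw effects. The overlap was 7418 probes, where 4337 would overlap by chance between independent lists and 525 in simulated unchanged groups sharing the same RNA. For the opposite directions it was 6490, against 3831 and 526.4. Fold changes correlated at r = -0.657 (simulated -0.685), with a covariance of -0.29 against a simulated -0.03. The simulated correlation follows from the RNA that the 2 contrasts share, whatever the size of the spread. That the observed correlation was no stronger therefore cannot decide whether the fold changes are related beyond it. The difference of low-Tw effects equals chilling in low-Tw plants less chilling in normal-Tw plants, so a real chilling effect enters it with its sign turned. Part of the overlap is therefore built in, and neither expected value allows for this. Shared normal-Tw RNA adds to it, and 2 profiles cannot be divided further, so these parts were not separated. With profiles as replicates the overlaps were 4035 and 3367 probes, against 1653 and 1459 by chance. A different quantity, the probes called the same way by chilling in normal-Tw and in low-Tw plants, came to 4513 higher and 4388 lower probes, against 3450 and 3109 by chance and 0.8 and 1 in simulated unchanged groups, with r = 0.0563 (simulated 0.0241).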

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

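The tests of dye effects, single RNAs, sampling hour and green tissue, and the overlaps expected for the heat shock and cold regulator genes, were chosen after the result was seen, and the counts over other arrangements of the arrays before. The bounds of the dye test of the cold regulators and of the tests of single RNAs were also revised after their values were seen. Genes chosen by their mean can have arrays near 0: 79 of the 821 probes called at least 2-fold with low Tw in non-chilled spikelets had 2 arrays within 0.25 of 0. With chilling only 1 of 2138 had, and with low Tw in chilled spikelets 1 of 3828. The heat shock genes were chosen on the chilling arrays, the cold regulators there and on those of low Tw in non-chilled spikelets. On arrays where its genes were chosen, a test of single RNAs weighs little.

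The low-Tw effect differed between chilled and non-chilled spikelets for 24222 probes. These genes and the count stood out because the test of the difference itself called them. Among the named genes, the positive ones were Os04g0372700 (7.59), Os09g0522000 (6.24), Os01g0606900 (5.00), Os02g0681200 (4.85), Os01g0733200 (4.67), Os04g0223500 (4.67), Os04g0610400 (4.65) and Os07g0529600 (4.43). The negative ones were Os01g0314800 (-8.62), Os01g0123900 (-8.35), Os03g0830500 (-8.33), Os04g0352400 (-7.84), Os12g0247700 (-7.29), Os05g0469600 (-7.13), Os05g0442400 (-6.93), Os04g0107900 (-6.73) and Os05g0519700 (-4.07). With RNA profiles as replicates Os03g0830500 did not pass (adjusted p = 0.0664). Part of 6 of the negative values came from arrays 1 and 3 of low Tw in non-chilled spikelets, which carry the same RNA profile. Without these arrays the differences were -5.74 for Os01g0314800, -5.58 for Os01g0123900, -4.51 for Os03g0830500, -4.66 for Os12g0247700, -5.24 for Os05g0469600 and -4.73 for Os05g0442400, smaller than the -7.79 of Os04g0352400.

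Of 57 heat shock genes chilling raised 22 at least 2-fold in normal-Tw plants, and all 22 were lower with low Tw in chilled spikelets, where 15.1 would be by chance between independent lists and 0.05 in simulated unchanged groups. Both comparisons hold the chilled normal-Tw RNA with opposite signs, so a high level in that condition alone gives both, and part of the excess may come from this shared RNA. A dye effect specific to these genes would raise them in both comparisons, since the dyes ran the same way, but their median with low Tw was -4.02, beyond their median absolute deviation of 1.54. A single RNA standing apart would leave some arrays near 0, but the array median nearest to 0 was -3.97 with low Tw in chilled spikelets and 3.57 with chilling, each beyond the spread of the genes on its array. The genes were chosen on the chilling arrays, so the value there weighs little. A single non-chilled RNA as the whole cause would set its 2 profiles at least 4-fold apart for each gene, since each rose at least 2-fold on average. Over all 36091 probes, which were not chosen, only 11 differed over 4-fold between these profiles, fewer than the 22 genes. For the 22 genes as a set, this argues against a single non-chilled RNA as the whole cause. The value with low Tw argues against a single chilled RNA. A different hour of sampling stays open, because clock genes also moved with chilling (median -0.85). Slide, which each comparison had to itself, and the biological effect of cool water, which the design names, stay open as well.

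With low Tw in non-chilled spikelets and with chilling in normal-Tw plants, 4 cold regulators (Os09g0522200, Os09g0522000, Os04g0572400 and the ICE1 gene Os01g0928000) of 13 were called lower by the main test, where 3.2 would be by chance between independent lists and 0.15 in simulated unchanged groups. Both comparisons hold the non-chilled normal-Tw RNA as reference, so a high level in that condition alone gives both falls, and the overlap may come from this shared RNA. With RNA profiles as replicates ICE1 did not pass for low Tw (adjusted p = 0.0569), nor Os04g0572400 for chilling (0.141). A dye effect as the whole cause would give the same fall with low Tw in chilled spikelets, at least the -2.08 of chilling, but their median there was 0.91 with a median absolute deviation of 1.01. A single RNA standing apart as the whole cause would leave 2 arrays near 0. The array medians nearest to 0 were -3.00 with low Tw and -1.38 with chilling, beyond the spread of the genes. These medians do not describe ICE1, which had a log2 ratio of only -0.29 with low Tw and -0.89 with chilling. The other genes had -2.90 to -4.28 with low Tw and -1.40 to -2.99 with chilling. With chilling, Os04g0572400 had only -0.62 and -0.68 on arrays 2 and 4. The genes were chosen for their fall on these same arrays, so this test cannot exclude a single RNA. A different hour of sampling stays open. Clock genes had a median of -0.85 with chilling and -0.32 with low Tw in non-chilled spikelets, their list passing only with chilling. Slide and the biological effect of the treatments stay open and untested.

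Of 53 photosynthesis genes, 38 were called lower and 5 higher with low Tw in chilled spikelets, but the list did not pass with an estimated correlation (adjusted p = 0.771). A dye effect equal on all arrays cancels in the difference of low-Tw effects, and 62.3% of the list was called lower there with RNA profiles as replicates, which argues against it. This share replaced a first test after that test was seen to leave a dye effect open, since the list median of -0.80 did not exceed the median absolute deviation of 1.07, and its bounds were set when the share was known. A smaller share of green tissue in those spikelets may contribute: 71.7% of the list was called lower, which leaves this open, as nearly all members would be lower together. Slide stays open too. A different hour of sampling was not tested for this list and stays open, as clock genes also moved in this comparison.

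Turning the sign of single arrays gives 8 arrangements per direct comparison, too few for a share under 0.05, and 1 of the 8 reached the real count in each. The real counts were 27451, 18651 and 24320 probes for low Tw in chilled spikelets, low Tw in non-chilled spikelets and chilling, and the highest others 0, 150 and 1. For the difference of low-Tw effects, 1 of 35 splits of the 8 arrays reached 24222 probes and the highest other gave 21, which would exclude chance only if the arrays were independent. For chilling in low-Tw plants, 1 of 96 sign arrangements reached 19457. The highest other gave 18412. It turned only 3 arrays, all of non-chilled low Tw, so it kept the real effects of the other comparisons, while 71 arrangements called 0 probes. All these counts treat arrays as independent. With 2 RNA profiles per condition they are not, so chance between RNA samples is not excluded by them.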

How the results depend on the processing

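The alternatives with RNA profiles, without the list removals and with chilling in low-Tw plants were chosen after the result was seen. Of the alternative values of named genes 2267 kept direction and call, 26 lost the call and 3 reversed; of list values 1137 kept both, 70 lost the call and 9 reversed; of counts 201 stayed within 1.5 times the main count and 13 did not, and the cause of these changes was not tested unless given. With RNA profiles as replicates, which leaves fewer units, 4251 probes were called for low Tw in non-chilled spikelets, 15091 for chilling, 14872 for the difference and 7402 for the overlap. Without the second profile of non-chilled normal-Tw RNA, which removes 4 arrays, low Tw in non-chilled spikelets had 12174. The 2-fold threshold, stricter by construction, left 3828 (low Tw, chilled), 821 (low Tw, non-chilled), 2138 (chilling), 4449 (difference), 2651 (chilling in low Tw) and 1342 (overlap). Chilling in normal-Tw against low-Tw plants gave an overlap of 8901. Without single arrays the counts ranged from 25860 to 27592, 15861 to 18372, 21859 to 24475, 23032 to 24064, 18007 to 19293 and 12751 to 13680 in that order. Median centring gave an overlap of 9253. It took the median of all probes from 0.0043 to 0.15 for low Tw in chilled spikelets and from 0.0106 to 0.12 for chilling. For chilling in low-Tw plants it went from -0.0046 to 0.24. As a result 64.0% (low Tw, chilled), 67.97% (low Tw, non-chilled), 61.9% (chilling), 62.0% (difference) and 74.5% (chilling in low Tw) of calls were higher, in place of 50.5%, 52.8%, 52.0%, 48.9% and 50.6%. There, HSP101 with chilling in low-Tw plants was 0.13, and list medians reversed to 0.12 (reactive oxygen), 0.20 (ribosomal) and 0.23 (proteasome) in chilled spikelets, 0.0939 (histones) and 0.16 (proteasome) in non-chilled ones, and 0.0371 (small heat shock) and 0.0012 (histones) with chilling in low-Tw plants. Scaling between arrays gave 0.79 for HSP101 and 0.093 for small heat shock genes with chilling in low-Tw plants. The dye term gave 0.27 for HSP101 there and -0.0018 for glutathione S-transferases in non-chilled spikelets. Aquantile moves only brightness and changed no ratio, and fits on the arrays of 1 comparison give no value for chilling in low-Tw plants. With the replicate number as a block, counts were 27965, 19715, 25090, 24913, 20437 and 14517, and the pistil list lost its call in the difference; same-numbered arrays of different comparisons correlated from -0.24 to 0.42 and did not always match best, so the number does not pair the arrays, some of which share RNA across comparisons under other numbers. Below-background signal limits ratios of the dimmest genes to bounds.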

Other observations

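On the 4 arrays of low Tw in non-chilled spikelets, the log2 ratio of Os03g0830500 was 7.42, 0.13, 7.45 and -0.57 in order of replicate number, and that of Os12g0247700 was 5.55, -0.20, 5.85 and 1.09. The LEA3 gene Os01g0314800 had 5.29, -0.52, 5.22 and -0.46, and the MYBS3 gene Os05g0442400 had 4.63, 0.51, 4.54 and -0.12. The pyruvate decarboxylase gene Os05g0469600 had 3.68, -0.00, 4.25 and 0.35. Neither the labels nor the series description separates these arrays.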
